A study of Mus musculus with 4 samples.

How the data were processed

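Bone marrow cells of C57BL/6 mice, sorted as negative for lineage markers and positive for Sca1 and cKit (LSK), were profiled in 4 inDrop libraries. The groups, taken from the labels, were wild-type (WT) untreated, WT imatinib, chronic myeloid leukaemia (CML) untreated and CML imatinib, with 1 library each. Per the labels' protocols, imatinib was given by gavage at 400 mg/kg on alternate days for 30 days, while another label of the same samples gives 4 weeks.

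Each deposited file is a matrix of genes by cells whose values are a normalized signal: within each file, every cell's values sum to about the same total, 2839.18. The submitters' processing notes name Partek 8.0, Bowtie 1.1.1 and the genome build GRCm38 (mm10); the role of each tool is not given in the sources used here. In every cell the values were multiples of a common step, so dividing by that step gave the UMI counts (unique molecular identifiers, 1 per captured transcript) back. The recovered values were whole for 100% of the entries, within a tolerance of 0.02. Each header holds 1 name more than there are value columns, and cell names repeat, so cells were taken by column position. The files list 32265 genes; 30443 of them (94.4%) match a symbol of the GENCODE vM21 annotation of GRCm38, from which coordinates were taken, 26 look like dates and 2 are repeated.

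Cells were kept with at least 500 UMIs, at least 200 detected genes and at most 20% of UMIs from mitochondrially encoded genes. For each library the UMIs of the kept cells were summed per gene and scaled to counts per 1000000 UMIs (CPM). Libraries were compared in pairs by the log2 ratio of CPM, with an exact conditional binomial (Clopper-Pearson) 95% interval. With 1 library per group there was no test, and the intervals cover counting error only. A gene counted as different when it was at least 2-fold apart, with at least 50 CPM and at least 50 UMIs in the higher library. The 4 comparisons were CML untreated versus WT untreated, CML imatinib versus CML untreated, WT imatinib versus WT untreated, and CML imatinib versus WT imatinib. The difference of the imatinib responses is the log2 ratio in CML minus that in WT. A gene with 0 UMIs in a library would be set to a floor of 3 counts, which is 0.228 CPM in the WT untreated, 0.364 in the WT imatinib, 0.141 in the CML untreated and 0.314 in the CML imatinib library.

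The design, the gene lists, the cell filter and the rule for named genes were written before the data were examined. Named genes are the 12 with the highest and the 12 with the lowest log2 ratio (ranked with 1 CPM added) that have at least 100 CPM and 50 UMIs in the higher library and a 2-fold difference, and the 8 at each end for the difference of the responses. Predicted genes named Gm or Rik, ribosomal protein genes, their pseudogenes and mitochondrially encoded genes were left out of the naming. From each list up to 4 members with at least 20 CPM were named, those with the largest absolute log2 ratio. In total 44 lists were fixed, of which 25 describe cell states or pathways. A list's median log2 ratio covers its genes with at least 10 CPM in either library, needs 3 such genes, and is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The pattern for ribosomal proteins also takes the kinase genes of the Rps6k family, such as Rps6ka1.

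For clusters, cells were scaled to 10000 UMIs, transformed by log(1+x), and reduced to 2000 variable genes, leaving out the sex-linked, ribosomal and mitochondrial lists. Then 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 were used. The numeric rule for cluster names was set after the data were examined. A name needs at least 3 markers of the class among the cluster's 25 leading genes, more than any other class has, at least 1 among the leading 10 and no fewer there than another class, and a marker UMI in at least 50% of its cells. Shares of cells have exact binomial intervals, and for a share of 0 the limit given is 3 counts of the library's cells. For the share of cells with G2 and M phase transcripts, each cell was thinned to 500 UMIs, and at least 2 UMIs from the list were required.

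Each result was recomputed under alternatives chosen with the design: at least 1000 UMIs per cell, no cell filter, TMM scaling with edgeR, scaling without ribosomal, mitochondrial and haemoglobin genes, the mean of single-cell CPM, thinning to 500 UMIs, Scrublet doublets left out, mature-cell clusters left out, other expression floors, and other settings of the clusters and of the G2 and M phase share. Chosen after the data were examined were the added alternatives (leaving out the top 5% of doublet scores, the plasma cell-like and T cell-like clusters, the erythroid-like cluster, or immunoglobulin and sex-linked genes; deeper cells thinned to 500 UMIs; each file split into 4 parts by column order; single clusters), the comparisons within clusters, and the genes Rpl9, Rps18, Tmsb10, Gm42418, Ctse, Anxa1, Elane and Mpo where they stand outside the naming rule. So was the criterion for calling a list higher or lower: a median at least 0.2 from 0 and outside the central 95% of the random lists. The mature-cell clusters are the neutrophil-like, erythroid-like, mast cell and basophil-like, T cell-like and plasma cell-like ones. Leaving them out keeps the monocyte and macrophage-like cluster and all unnamed clusters, including cluster 4, which is led by stromal genes. Scrublet marked 0 cells as doublets in each of the 4 libraries, so it has not worked on these cells, and doublets remain in the counts.

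The size rule was tried on simulated counts, drawn for both libraries from the summed profile of the second library of a comparison. These counts hold Poisson counting error only. Variation between mice, preparations and cells was left out, so the simulation cannot show how often such variation passes the rule. In the simulation of CML untreated versus WT untreated, 100% of 50 genes made 2.5-fold higher and 98% of 50 genes made 4-fold lower passed, 0 of 3409 unchanged genes passed, and the intervals covered the true ratio for 95.5% of them. In the simulation of CML imatinib versus CML untreated, 98% of 50 genes made 2.5-fold lower passed and 0 of 3494 unchanged genes did. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.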

Results

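Single-cell transcriptomes of mouse bone marrow LSK cells were measured with inDrop, which captures cells in droplets with barcoded beads and counts transcripts by unique molecular identifiers (UMIs). LSK cells lack lineage markers and carry Sca1 and cKit, a gate that holds the stem and multipotent progenitor cells of the marrow. The mice were wild-type (WT) or had chronic myeloid leukaemia (CML), a leukaemia driven by the BCR-ABL tyrosine kinase. They were untreated or had received imatinib, an inhibitor of the ABL, KIT and PDGF receptor kinases. Each of the 4 groups had 1 library, so no difference has a replicate check, no test was made, and every interval covers counting error only.

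The WT untreated library held 3030 kept cells and 13153658 UMIs, with a median of 3637.5 UMIs per cell. The WT imatinib library held 4187 kept cells and 8245224 UMIs, with a median of 1486. The CML untreated library held 3032 kept cells and 21283108 UMIs, with a median of 5160.5. The CML imatinib library held 5139 kept cells and 9540004 UMIs, with a median of 1198. The shallowest deposited cell had 1001 and 1006 UMIs in the WT and CML untreated libraries, but 200 UMIs in each imatinib library. Treatment and depth per cell therefore went together.

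Kit, the stem cell factor receptor used in the sort and a target of imatinib, was at 136 CPM (interval 129.6 to 142) in the WT untreated and 176 CPM (167 to 185.5) in the WT imatinib library. It was at 149 CPM (144 to 154) in the CML untreated and 143 CPM (136 to 151) in the CML imatinib library. Ly6a, which encodes Sca1, was at 192 CPM (185 to 199.8) in the WT untreated library and at 95.8 CPM (91.7 to 100.1) in the CML untreated library. Of these UMIs, 1484 of 2527 in WT and 398 of 2039 in CML lay in plasma cell-like cells, 94 and 40 in number, and in the largest cluster of the untreated libraries Ly6a was at 79.5 and 75.95 CPM. In the imatinib libraries it was at 49.6 CPM in WT and 51.05 CPM in CML. Flt3, a receptor of early lymphoid progenitors, was at 171 and 158 CPM in the WT and CML untreated libraries, against 24.98 and 13.52 CPM in the imatinib libraries. Cd34, a sialomucin of progenitor cells, was at 428, 173, 319 and 159 CPM in the WT untreated, WT imatinib, CML untreated and CML imatinib libraries. Ly6e, a relative of Ly6a, was at 1322, 1251, 965 and 1152 CPM in the same order.

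Abl1, the main target kinase of imatinib, was at 98.4 CPM in the WT untreated and 112 CPM in the CML untreated library, against 67.8 and 64.3 CPM in the WT and CML imatinib libraries. Its relative Abl2 was at 30.7, 17.5, 36.55 and 18.9 CPM in the WT untreated, WT imatinib, CML untreated and CML imatinib libraries. Bcr was at 18.3, 27.9, 17.1 and 28.1 CPM in that order. Counts per gene do not separate a fusion transcript from those of Abl1 and Bcr. Csf1r, the macrophage colony-stimulating factor receptor, was at 57.3, 48.4, 32.3 and 31.8 CPM, and Pdgfrb at 14.4, 11.04, 14.7 and 12.8 CPM. Pdgfra, Ddr1 and Ddr2 were under 2 CPM except in the CML imatinib library, where Pdgfra was at 7.34 CPM and Ddr2 at 5.975 CPM. On GRCm38, Kit lies on chromosome 5 at 75574916 to 75656722, Ly6a on chromosome 15 at 74994877 to 74998031, Abl1 on chromosome 2 at 31688376 to 31804227 and Bcr on chromosome 10 at 75060592 to 75184921.

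Xist, the RNA that silences an X chromosome in female cells, was at 2375 CPM in the CML untreated library, 94.97 CPM in the CML imatinib library, 1.52 CPM in the WT untreated library and 3.15 CPM in the WT imatinib library. The Y-linked gene Ddx3y was at 1.504 CPM in the CML untreated library and at 43.6, 29.35 and 45.2 CPM in the WT untreated, WT imatinib and CML imatinib libraries. Eif2s3y was at 7.85 CPM in the CML untreated library and at 63.0, 40.02 and 41.8 CPM in the same other libraries. Kdm5d was at 7.001 and Uty at 2.21 CPM in the CML untreated library. The sex-linked list had medians of -3.01, 2.41, -0.61 and 0.39 for CML untreated versus WT untreated, CML imatinib versus CML untreated, WT imatinib versus WT untreated and CML imatinib versus WT imatinib. The sex markers thus set the CML untreated library apart, and Xist also differed between the imatinib libraries, so each comparison that uses a CML library includes a difference in sex markers.

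The kept cells fell into 10 clusters, 7 of which carried enough markers for a name. A granulocyte-monocyte progenitor-like cluster of 5251 cells held 58.4% (56.9 to 59.9) of the WT imatinib and 51.3% (49.9 to 52.7) of the CML imatinib cells. It held 3.27% (2.66 to 3.96) of the WT untreated and 2.41% (1.89 to 3.02) of the CML untreated cells. The largest cluster of the untreated libraries, unnamed and led by Dntt, Rgs1 and Ctla2a, held 70.1% of the WT untreated and 68.3% of the CML untreated cells, against 1.6% and 0.798% of the WT and CML imatinib cells. With at least 1000 UMIs per cell and new clusters, the largest untreated cluster, then named megakaryocyte and platelet-like, held 6.80% and 5.75% of the WT and CML imatinib cells. Shares rest on a floor of 500 UMIs unless another is given, with median depths that differed as given above. An untreated and an imatinib library therefore shared few cells of either large cluster.

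Smaller clusters also differed between libraries. Neutrophil-like cells made up 3.73% of the WT imatinib and 5.12% of the CML imatinib library, and 0 cells of the untreated libraries, which allows up to 0.0990% in WT and 0.0989% in CML. The imatinib shares of this class depend on the setting, with 6.425% in WT and 13.04% in CML at Leiden resolution 1.0 and 5.65% and 14.97% with at least 1000 UMIs per cell. Mast cell and basophil-like cells were 0.264% and 0.957% of the WT and CML untreated cells and 3.13% and 3.06% of the WT and CML imatinib cells. With values centred within each library, and with at least 1000 UMIs per cell, the WT untreated share was 0.066%, or 2 cells. Erythroid-like cells were 2.01%, 0.430%, 3.83% and 5.001% of the WT untreated, WT imatinib, CML untreated and CML imatinib cells. At resolution 1.0 the shares were 4.26%, 0.502%, 5.05% and 5.04% in that order, so the gap between CML and WT untreated shrank. With values centred within each library the class split by treatment: 1 cluster held 251 CML and 15 WT imatinib cells and 0 untreated cells, another 114 CML and 65 WT untreated cells with 0 CML and 2 WT imatinib cells. T cell-like cells were 3.53% and 4.12% of the WT and CML untreated cells, with 1 cell in the WT imatinib library and 0 in the CML imatinib library. Plasma cell-like cells were 3.10% of the WT untreated, 1.32% of the CML untreated and 0.143% of the WT imatinib cells, and 0 cells of the CML imatinib library, which allows up to 0.0584%. The gate should leave out mature T, plasma, neutrophil, mast and erythroid cells. It is meant for stem and multipotent progenitor cells, but 58.4% of WT and 51.3% of CML imatinib cells were granulocyte-monocyte progenitor-like. Whether those cells met the gate was not tested. Monocyte and macrophage-like cells were 12.1% and 15.8% of the WT and CML untreated cells and 2.17% and 0.915% of the WT and CML imatinib cells. With values centred within each library they were 37.2% and 36.8% of the WT and CML untreated cells, and at resolution 1.0 they were 8.335% and 2.88% of the WT and CML imatinib cells. Their median UMI count was 2.06 times that of their own library, so doublets among them remain open, since Scrublet marked 0 cells in each library. The unnamed clusters 3 and 4 had medians of 1002 and 788.5 UMIs and held 19.9% and 10.53% of the WT imatinib, 16.95% and 16.9% of the CML imatinib, 3.63% and 2.01% of the WT untreated and 2.08% and 1.19% of the CML untreated cells.

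**Figure D1:**
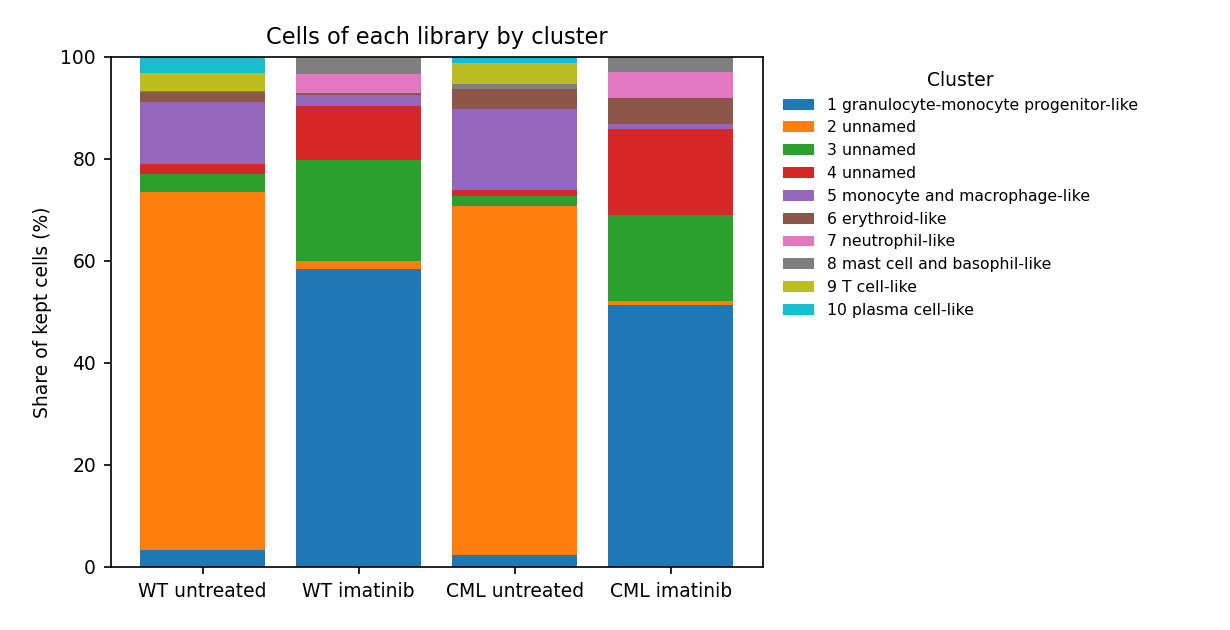
Share of each library's kept cells (%, vertical axis) in each of 10 clusters (colours), 1 bar per library. The granulocyte-monocyte progenitor-like cluster takes 58.4% of the WT imatinib and 51.3% of the CML imatinib cells, and the unnamed cluster 2 takes 70.1% of the WT untreated and 68.3% of the CML untreated cells.

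The comparison of CML untreated with WT untreated asks how LSK cells of leukaemic mice differ from normal ones before treatment. Heat shock genes were higher in CML: Hspa1b, an inducible HSP70 chaperone, was 11.1-fold higher (10.8 to 11.5), its near-identical copy Hspa1a 7.17-fold (6.84 to 7.52), and Hsph1, an HSP110 chaperone, 3.41-fold (3.24 to 3.59). Immediate early genes were higher as well: Fosb, a subunit of the AP-1 transcription factor, was 3.07-fold higher (2.94 to 3.22), and Dusp1, a phosphatase that switches off MAP kinases, 2.51-fold (2.41 to 2.61). Immunoglobulin genes were lower in CML, with Igkc 3.55-fold lower (3.52 to 3.58) and Jchain, which joins IgA and IgM units, 3.53-fold lower. Of the Igkc UMIs 97.6% in WT and 95.1% in CML lay in plasma cell-like cells, and without the plasma cell-like and T cell-like cells the log2 ratio of Igkc was -0.95, under 2-fold. Irf8, a transcription factor of monocyte and dendritic cell development, was 2.43-fold lower (2.28 to 2.58).

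Of 3824 genes measured, 20 were at least 2-fold higher and 15 at least 2-fold lower in CML, 0.915% in all. The transcription factors Klf2 and Klf6 were 2.49-fold (2.32 to 2.68) and 2.43-fold (2.32 to 2.53) higher, and Btg2, an antiproliferative gene, 2.39-fold (2.27 to 2.51). The mast cell proteases Cma1 and Tpsb2 were 948-fold (324 to 4599.9) and 1722-fold (309 to 68033) higher, from 3 and 1 UMIs in WT, and the mast cell carboxypeptidase Cpa3 was 2.67-fold higher (2.52 to 2.83). Xist was 1562-fold higher (1011 to 2557). Iglc1 was 90.1-fold (69.1 to 119.9), Ighg2b 37.3-fold (30.49 to 46.2), Igha 3.49-fold and Ighm 2.36-fold lower. Ly86, a partner of a Toll-like receptor homologue on B cells and myeloid cells, was 2.31-fold lower, Hes1, a Notch target, 2.04-fold lower (1.88 to 2.20), and Ly6a 2.01-fold lower (1.89 to 2.13). Without plasma cell-like and T cell-like cells Ly6a was at -0.18, so its call rests on those cells. Reads of Hspa1a and Hspa1b, of Tpsb2 and its relatives, and of the immunoglobulin genes could be split between copies, so their single values are uncertain.

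Among the fixed lists, 8 of 16 immediate early and dissociation genes were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.02, above all 10000 matched random lists; Atf3, a stress-induced transcription factor, was at 1.53. For heat shock, 4 of 10 genes were higher and 0 lower, with a median of 0.83, above all random lists. The cochaperone Dnajb1 was 2.26-fold higher. The STAT5 targets had a median of 0.27 (percentile 98.6) with 0 of 11 genes past 2-fold, led by Socs3 at 0.96 and the survival gene Mcl1 at 0.83. The TNF and NF-kB response list had a median of 0.29 (percentile 99.6), with 1 of 12 genes lower. For mast cells and basophils, 6 of 8 genes were higher, with a median of 1.45, including the granule protease Gzmb at 3.498 and the IgE receptor chain Fcer1a at 2.42. The erythroid list had a median of 0.28 (percentile 99.7). Under TMM scaling the STAT5, TNF and NF-kB and erythroid medians were 0.10, 0.12 and 0.09, and none of these 3 lists was called higher. Without the mature-cell clusters the mast cell and erythroid medians were -0.60 and -0.17, Cpa3 was at -0.62 and Ighg2b at 1.67.

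Lists that were lower in CML were those of plasma cells (5 of 5 genes, median -1.82), B cells (4 of 4, median -1.33), dendritic cells (1 of 3, median -0.87), monocytes and macrophages (0 of 6 past 2-fold, median -0.72) and the type I interferon response (0 of 19, median -0.26, percentile 0.01). Csf1r was at -0.83, F13a1, a clotting factor chain of monocytes, at -0.89, and Rtp4, an interferon-induced gene, was 1.99-fold lower. The LSK sort genes had a median of -0.43, but -0.07 (percentile 35.7) within the largest cluster of the untreated libraries. The HSC (haematopoietic stem cell), lymphoid-primed, megakaryocyte and granulocyte-monocyte progenitor lists had medians of 0.15, -0.15, 0.03 and -0.19, and the neutrophil list -0.15, with Lcn2, an iron-binding neutrophil protein, at 1.85. The target kinase list had a median of 0.08. The S phase and the G2 and M phase lists had medians of 0.02 and 0.00, and the CML stem cell marker list 0.03. TMM scaling moved the median of all genes by -0.17 and the split to 15 higher and 23 lower. Without plasma cell-like and T cell-like cells, 9 genes were at least 2-fold lower.

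The comparison of CML imatinib with CML untreated asks how drug treatment goes along with the state of leukaemic progenitors. Neutrophil granule genes were far higher with imatinib: S100a9, a subunit of the calprotectin complex, was 1143-fold higher (869 to 1535.5), its partner S100a8 278-fold (244 to 317), and the antimicrobial peptide gene Camp 3894-fold (1668 to 11995), from 5 UMIs untreated. The progenitor granule enzyme Mpo, myeloperoxidase, was 7.25-fold and Elane, neutrophil elastase, 6.92-fold higher. Genes of early progenitors were lower: Dntt, the DNA polymerase of lymphoid progenitors, was 15.1-fold lower (12.04 to 19.1), Flt3 11.7-fold (9.78 to 14.01), and Rgs1, a regulator of G protein signalling, 32.8-fold (28.3 to 38.3). Egr1, an immediate early transcription factor, was 26.6-fold lower (23.7 to 29.96).

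Of 4265 genes, 401 were at least 2-fold higher and 339 at least 2-fold lower with imatinib, 17.4% in all. Further neutrophil genes among the highest were Ngp, at 3751-fold (1607 to 11554), the iron-binding granule protein gene Ltf, at 844-fold (444 to 1847), Retnlg, at 1053-fold, and Chil3, a chitinase-like gene, at 388-fold (245 to 655). The basophil protease Prss34 was 1038-fold higher (503 to 2584), and Fcnb, a lectin of granulocyte precursors, 53.4-fold (42.4 to 68.05). The haemoglobin genes Hbb-bs and Hba-a2 were 181-fold (148 to 223) and 208.5-fold (149.6 to 299.9) higher, though reads could be split between haemoglobin copies. The chemokine gene Cxcl12, made by marrow stroma, was 193-fold higher (132 to 294). Among the lowest were Igkc at 1198-fold, Igha at 936.5-fold and Jchain at 564-fold lower, with Ighm 11.2-fold lower. Without plasma cell-like and T cell-like cells Ighm was at -0.58 on the log2 scale, while Igkc stayed over 2-fold lower. Xist was 25.005-fold lower (23.4 to 26.7). Tnfaip3, an inhibitor of NF-kB, was 12.4-fold lower (10.3 to 14.97), Ctla2a, a cysteine protease inhibitor gene, 10.9-fold, and Zfp36, which promotes decay of cytokine mRNA, 9.46-fold (9.06 to 9.88).

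By lists, 14 of 15 neutrophil genes were at least 2-fold higher and 0 lower, with a median of 6.87, and 12 of 15 granulocyte-monocyte progenitor genes were higher, with a median of 1.59, both above all random lists. Cebpe, a transcription factor of granulocyte maturation, was at 3.98, Ly6c2 at 3.62 and the Fc receptor Fcgr3 at 3.02. The monocyte list had 4 of 8 genes higher and a median of 0.92, with Fn1, fibronectin, at 2.98. For the HSC list 6 of 10 genes were lower, with a median of -1.54, below all random lists; the stem cell transcription factors Hlf, Meis1 and Mecom were at -2.20, -1.81 and -1.55. The lymphoid-primed list had 5 of 7 genes lower and a median of -1.82. The megakaryocyte list had 7 of 9 genes lower and a median of -1.93, with Pf4, platelet factor 4, at -3.43. The erythroid list had 12 of 17 genes higher and a median of 1.89, and -1.11 without the mature-cell clusters. Mast cell and basophil genes had 5 of 9 higher and a median of 1.02, and all 6 measured stromal genes were higher, with a median of 5.16. The plasma cell, T cell and B cell lists had medians of -9.14, -2.78 and -3.48, with all 3, 6 and 3 measured genes lower. The B cell median was 0.56 without the mature-cell clusters.

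Several signalling lists had lower medians in the CML imatinib than in the CML untreated library, which also differed in their clusters. List medians within clusters were not computed for imatinib versus untreated in either genotype. A change inside cells is therefore not told apart from a change of the cell mixture. The JAK-STAT and MAPK pathway lists, at 0.17 and -0.07, were not called. Of the immediate early genes 15 of 16 were lower, with a median of -2.39, and Atf3 was at -4.16. All 7 ERK feedback genes, which the MAP kinase pathway induces, were lower, with a median of -1.79, Dusp5 at -4.38 and Dusp6 at -2.35. Of the STAT5 targets 7 of 11 were lower, with a median of -1.31, Socs3 at -3.04 and Mcl1 at -2.23. The TNF and NF-kB list had 8 of 13 genes lower (median -1.05), the heat shock list 5 of 10 (median -0.99) and the interferon list 5 of 16 (median -0.66), while Rsad2, an antiviral gene, was at 2.37. The quiescence list had 3 of 8 genes lower and a median of -0.81, and the TGF-beta list 4 lower and a median of -0.55. The Wnt and mTOR lists had medians of -0.49 and -0.47, with 2 mTOR genes higher and 2 lower of 16. The p53 list, with a median of -0.51, was not called lower (percentile 2.88, 1 gene higher and 1 lower of 10). Oxidative phosphorylation had a median of 0.36 (percentile 99.9) and ribosomal proteins 0.41. A shift by the -0.32 of TMM scaling would take both medians under the limit of 0.2 for a call. MHC class II genes had a median of -0.88, dendritic cell genes -1.21 and mitochondrially encoded genes -0.42. TMM scaling moved the median of all genes by -0.32 and the split from 401 and 339 to 202 and 716.

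The comparison of WT imatinib with WT untreated shows what goes along with the drug in normal mice. Here too neutrophil and basophil genes were higher: S100a9 was 765-fold (545 to 1112) and S100a8 187-fold (159.6 to 219.6) higher. Elane was 7.96-fold and Mpo 7.05-fold higher. Dntt was 23.0-fold lower (18.1 to 29.7), Rgs1 32.6-fold (28.0 to 38.1), Egr1 12.5-fold (11.05 to 14.1), and Hes1 83.4-fold lower (46.5 to 167). The erythroid carbonic anhydrase genes Car1 and Car2 were 9.62-fold (8.16 to 11.4) and 9.29-fold (8.48 to 10.2) lower, while in CML their log2 ratios were 0.76 and 0.25.

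Of 4092 genes, 310 were at least 2-fold higher and 223 at least 2-fold lower, 13.03% in all. Prss34 was 9867-fold higher (interval from 1770.3) from 1 UMI, and Camp, Ngp and Retnlg were 3635-fold (from 1006), 3265-fold (from 903) and 1301-fold (from 359.6) higher, each from 2 UMIs in the untreated library. Chil3 was 539.5-fold (231 to 1664), Ltf 426-fold (182 to 1313), Fcnb 101.5-fold (71.7 to 149), Lcn2 42.2-fold (35.9 to 49.9), and the antimicrobial gene Wfdc21 29.6-fold (24.99 to 35.3) higher. Clec4a2, a lectin of myeloid cells, was 28.7-fold higher (22.1 to 37.9). Igha was 1413-fold (933 to 2255), Jchain 103-fold and Igkc 24.5-fold lower, and Iglc1 was 1921-fold lower (from 344) with 1 UMI left. Ctla2a was 11.9-fold and F2r, a thrombin receptor, 8.57-fold lower (7.14 to 10.4).

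In WT, 14 of 15 neutrophil genes (median 7.54) and 13 of 15 granulocyte-monocyte progenitor genes (median 1.92) were at least 2-fold higher, with Cebpe at 4.94 and Ly6c2 at 3.15. The mast cell and basophil list had 7 of 9 genes higher (median 2.90), with Cma1 at 7.31 and Mcpt8, a basophil protease, at 4.38. The monocyte list had 3 of 8 higher (median 0.86). The HSC list had 9 of 10 genes lower (median -1.52), the lymphoid-primed list 4 of 6 (median -1.60), the LSK sort genes 3 of 5 (median -1.30), and the megakaryocyte list 5 of 9 (median -1.75), although Ppbp, a platelet chemokine, was at 4.70. The erythroid list had 9 of 11 genes lower and a median of -2.55, with Gata1, the master regulator of red cells, at -3.45. Immediate early genes (14 of 16 lower, median -1.67), ERK feedback genes (6 of 7, median -2.24), STAT5 targets (8 of 10, median -2.01), TNF and NF-kB genes (8 of 13, median -1.29) and interferon genes (12 of 19, median -1.32) were lower. Nr4a1, an immediate early nuclear receptor, was at -5.00 and Cish, a STAT5-induced inhibitor, at -2.55. The heat shock list had 0 of 10 genes past 2-fold (median -0.12). The T cell, plasma cell and B cell lists had medians of -2.93, -6.69 and -3.44, the MHC class II list -1.20 with its chaperone Cd74 at -2.75, and the dendritic cell list -1.08. The quiescence, TGF-beta, mTOR, p53 and Wnt lists had medians of -1.02, -0.54, -0.42, -0.42 and -0.27, and the ribosomal and mitochondrial lists 0.34 and -0.69. Of these, the p53 (percentile 5.5) and Wnt (percentile 10.2) lists were not called lower. TMM scaling moved the median of all genes by -0.25 and the split from 310 and 223 to 207 and 473.

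Across 4420 genes, the log2 ratios of imatinib over untreated in CML and in WT had a Pearson r of 0.80 and a Spearman rho of 0.79; genes are not independent replicates, and these comparisons share no library. These are the genes with at least 50 CPM and 50 UMIs in any of the 4 libraries, a wider set than in each comparison alone. Of 415 of them at least 2-fold higher in CML and 330 in WT, 245 were higher in both, against 31.0 for independent lists. Of 348 genes lower in CML and 251 in WT, 183 were lower in both, against 19.8. Only 21 genes were at least 2-fold apart in opposite directions, some with few UMIs in WT. Ribosomal protein genes Rpl9 and Rps18, chosen after their values were seen, were 9.92-fold and 8.69-fold higher in WT and 12.2-fold and 6.87-fold higher in CML. Tmsb10, an actin-binding gene, was 5.46-fold and 6.44-fold lower. Rpl9 and Rps18 have many pseudogenes, so reads could be split between copies.

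**Figure D2:**
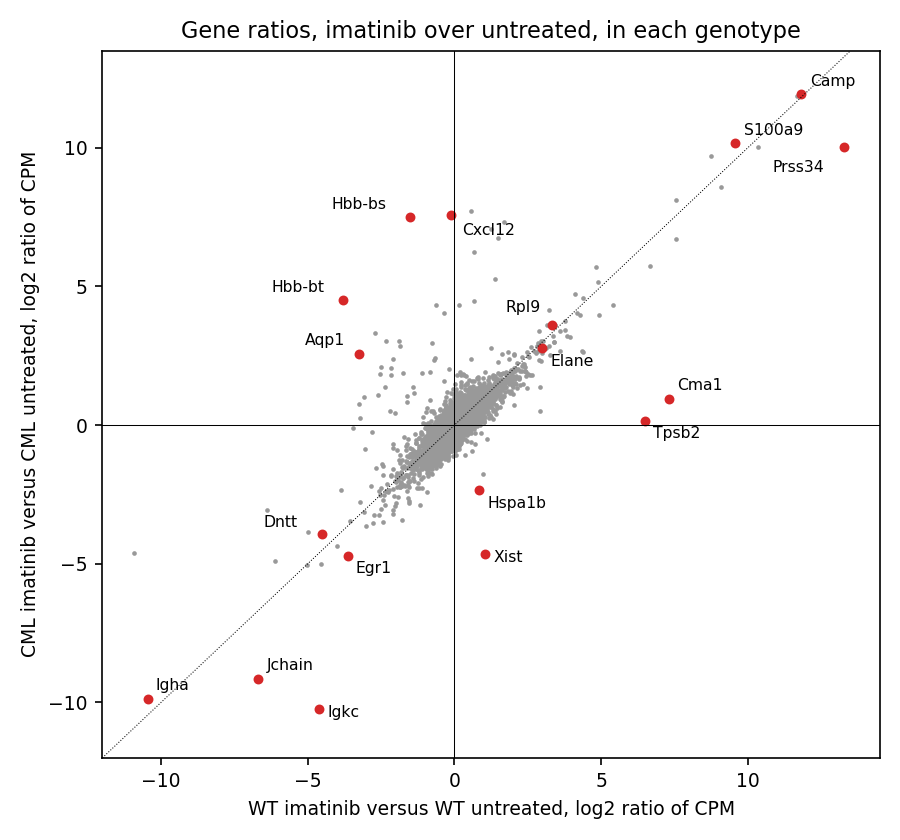
Each point is a gene, with its log2 ratio of CPM for WT imatinib versus WT untreated (horizontal) and CML imatinib versus CML untreated (vertical); red points are labelled genes and the dotted line marks equal ratios. Across 4420 genes r was 0.80, and Hbb-bs, Hbb-bt and Aqp1 were higher in CML but lower in WT.

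The comparison of CML imatinib with WT imatinib asks how leukaemic and normal progenitors differ under the drug. Red cell genes were higher in CML: the haemoglobin genes Hbb-bs, Hbb-bt and Hba-a2 were 358-fold (229 to 594), 295-fold (193 to 477) and 257-fold (143 to 515) higher, with reads that could be split between copies. The Rh blood group gene Rhd was 82.2-fold (50.5 to 144) and the water channel gene Aqp1 45.9-fold (35.9 to 59.6) higher. Stromal genes were higher too, with Cxcl12 at 144-fold (85.9 to 264.5) and Sparc, a matrix glycoprotein gene, at 26.5-fold (19.4 to 37.0). Igkc was 174-fold (125 to 249.8) and Ighm 4.91-fold (4.45 to 5.42) lower, and Prss34 2.20-fold lower (2.11 to 2.29). Of the WT imatinib Igkc UMIs 96.9% lay in 6 plasma cell-like cells, and without plasma cell-like and T cell-like cells the log2 ratios were -2.45 for Igkc and -0.42 for Ighm.

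Of 3914 genes, 91 were at least 2-fold higher and 7 at least 2-fold lower in CML, 2.504% in all. With the mean of single-cell CPM 36 were higher, 26 of them among the 91, and with cells thinned to 500 UMIs 36 were higher, 27 of them among the 91. Ermap, an erythroid membrane protein gene, was 25.9-fold (18.5 to 37.4), Car1 19.3-fold (16.4 to 22.8), Car2 14.4-fold (13.1 to 15.8) and Blvrb, a haem pathway reductase gene, 15.8-fold (12.7 to 19.98) higher. Tpsb2 was 21.2-fold higher (16.2 to 28.2). Of the erythroid list 16 of 17 genes were higher (median 4.27), and all 6 stromal genes (median 4.63), with Dcn at 5.62 and the collagen gene Col1a2 at 3.93. In the CML imatinib library 97.8% of the Hbb-bs UMIs lay in erythroid-like cells, and 82.9% of its Cxcl12 UMIs lay in 10 cells. Without the erythroid-like cluster 30 genes were at least 2-fold higher. Without the mature-cell clusters 25 were higher and 3 lower, and Prss34 was at 0.36.

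The granulocyte-monocyte progenitor list was slightly lower in CML (0 of 15 genes past 2-fold, median -0.38, below all random lists), with Ly6c2 at -0.62, Irf8 at -0.52 and Elane at -0.48. Within the granulocyte-monocyte progenitor-like cluster alone this list was at -0.06 (percentile 55.1), so the call is lost there. The neutrophil list was slightly higher (1 of 15, median 0.45), with Ltf at 1.14 and Ngp at 0.83. Of the mast cell and basophil list 3 of 9 genes were higher and 1 lower (median 0.02), with Cma1 at 3.53 and Cpa3 at 1.67. The monocyte, megakaryocyte and lymphoid-primed lists had medians of -0.34, -0.33 and -0.39, with the platelet chemokine gene Ppbp at -2.78 and Flt3 at -0.89. The HSC list had 2 of 8 genes higher (median 0.26), among them Mllt3, a transcriptional regulator of stem cell maintenance, at 1.42. The interferon list had 3 of 13 higher (median 0.24), with Rsad2 at 3.87 and the exonuclease gene Isg20 at 2.28. Neither the HSC list (percentile 91.3) nor the interferon list (percentile 94.2) was called higher. The S phase list (median 0.16) and the G2 and M phase list (median 0.14) lay at percentile 99.9. Within the granulocyte-monocyte progenitor-like cluster these lists were at -0.10 (percentile 4.03) and 0.01 (percentile 88.0). The mitochondrial list had a median of 0.31 over the libraries. The LSK sort genes, target kinases, STAT5 targets, ERK feedback, immediate early and heat shock lists had medians of -0.12, -0.03, 0.16, 0.02, 0.15 and 0.20. The CML stem cell marker list had a median of -0.25 (percentile 0.76), and 0.09 in deeper cells thinned to 500 UMIs. The B cell list had 2 of 3 genes lower (median -2.29). TMM scaling moved the median of all genes by -0.24 and the split from 91 and 7 to 55 and 12.

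**Figure D3:**
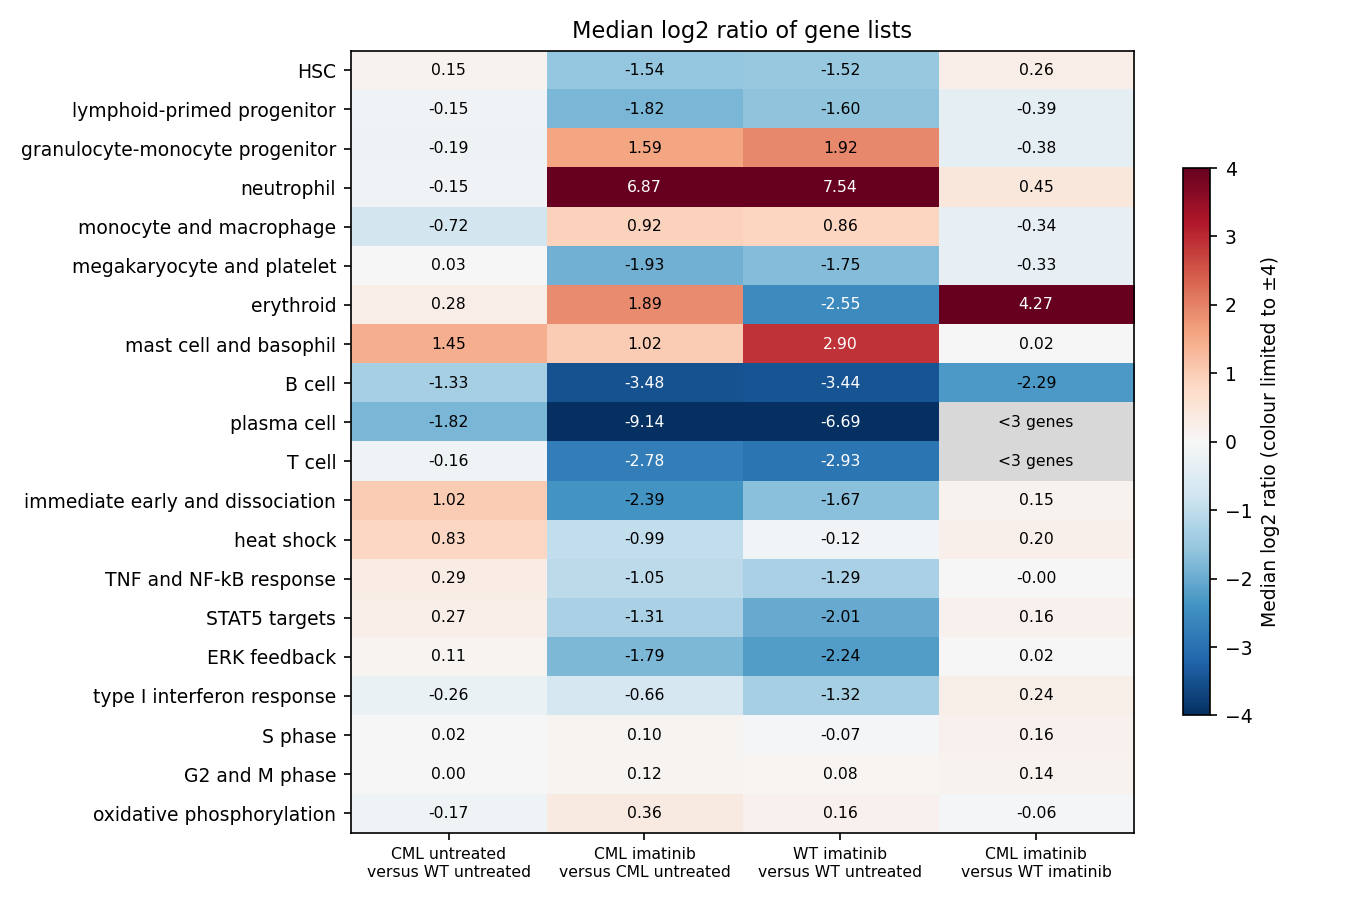
Median log2 ratio of CPM (colour and number) of the measured genes of 20 gene lists (vertical axis) in the 4 comparisons (horizontal axis); grey marks lists with under 3 measured genes. The granulocyte-monocyte progenitor list is at 1.59 and 1.92 for imatinib versus untreated in CML and WT, and the erythroid list at 4.27 for CML versus WT under imatinib.

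The difference of the responses asks which genes had another ratio to untreated in CML than in WT. Hbb-bs was at 7.498 in CML and -1.505 in WT, a difference of 9.003 on the log2 scale, and Hbb-bt at 4.51 and -3.81, a difference of 8.32. Cxcl12 (7.70), Hba-a2 (7.16), Iglc1 (6.28), Aqp1 (5.82), Rhd (5.39) and Ermap (4.4) followed. At the other end were Cma1 (-6.36), Tpsb2 (-6.34), Xist (-5.70), Igkc (-5.61), Prss34 (-3.25), Hspa1b (-3.17), Hspa1a (-2.74) and Jchain (-2.45). Prss34 had 1 and 7 UMIs in the WT and CML untreated libraries. Its response intervals were wide (8.98 to 11.3 in CML, 10.79 to 18.6 in WT), so the size of the difference is uncertain. The intervals overlapped, but an interval of the difference itself was not computed, so the overlap does not decide its direction. Iglc1 had 1 UMI in each imatinib library. Hspa1b was lower with imatinib in CML (-2.33) and higher in WT (0.84). It was at 322.8 and 3588 CPM in the WT and CML untreated libraries and at 577.9 and 715 CPM in the imatinib ones. Cma1 was at 0.228 and 216.3 CPM in the WT and CML untreated libraries and at 36.1 and 418 CPM in the imatinib ones. For both genes the genotypes were further apart untreated than under imatinib. In the absence of mature-cell clusters Cma1 was at 1.17, Tpsb2 at 2.99 and Jchain at 0.76, so these directions rest on those cells.

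Of 4420 genes, 97 had a difference of at least 1 and 41 of at most -1. These counts depend on the processing: 37 were higher with the mean of single-cell CPM, 79 lower with cells thinned to 500 UMIs, 33 higher and 22 lower without the mature-cell clusters, and 31 higher without the erythroid-like cluster. The erythroid list had 15 of 17 genes higher (median 4.02), the stromal list 6 of 6 (median 4.03) and the interferon list 7 (median 0.43). The mast cell list had 5 of 9 lower (median -1.59), the immediate early list 5 lower (median -0.71) and the heat shock list 3 lower (median -0.52). The plasma cell list had a median of 1.20, but -0.16 with cells thinned to 500 UMIs, and the megakaryocyte list a median of -0.40, but 0.02 in deeper cells thinned alike. The mast cell list had a median of 1.25 without the mature-cell clusters.

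Several lists had medians within the central 95% of the random lists, given here as CML untreated versus WT untreated, CML imatinib versus CML untreated, WT imatinib versus WT untreated and CML imatinib versus WT imatinib. MYC targets had medians of 0.12, -0.11, -0.18 and 0.07, although Myc itself was 2.80-fold lower with imatinib in CML. Glycolysis had 0.02, 0.28, 0.32 and -0.15, and cholesterol synthesis 0.13, -0.19, -0.09 and 0.03. The JAK-STAT pathway had 0.01, 0.17, 0.15 and 0.01 and the MAPK pathway -0.03, -0.07, -0.04 and 0.01. The BCL2 family had 0.10, 0.24, -0.06 and 0.08, and drug transporters 0.06, -0.25, -0.33 and -0.16. The CML stem cell list was at -0.15 and -0.10 for imatinib in CML and WT. Its member Msi2, an RNA-binding regulator of leukaemic stem cells, was however at -2.19 and -1.79. For CML versus WT imatinib this list was called lower, with 0 of 10 genes past 2-fold. That call was lost in deeper cells thinned to 500 UMIs (median 0.09). NK cell, endothelial and eosinophil lists had too few measured genes for a median.

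Transcripts of the G2 and M phase were found, with each cell thinned to 500 UMIs, in 44.0% (42.2 to 45.8) of the WT untreated and 47.8% (46.0 to 49.6) of the CML untreated cells. They were found in 61.1% (59.5 to 62.5) of the WT imatinib and 60.1% (58.7 to 61.4) of the CML imatinib cells. As background, the share was 5.32% in WT untreated and 5% in CML untreated plasma cell-like cells (cluster median 5578 UMIs) and 24.3% in WT untreated T cell-like cells (1755 UMIs). Among neutrophil-like cells it was 48.7% in the WT imatinib and 57.0% in the CML imatinib library (cluster median 1090 UMIs). Neutrophils do not divide once mature, but the maturity of these cells was not determined, so their share is not read as background. Without thinning the shares were 80.4% and 88.5% in the WT and CML untreated libraries and 83.5% and 81.2% in the WT and CML imatinib libraries, so the order of the libraries depends on depth. For imatinib versus untreated the G2 and M phase list had medians of 0.12 (percentile 88.7) in CML and 0.08 (percentile 83.5) in WT. It was called in neither. Cycling is not read from these shares alone.

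**Figure D4:**
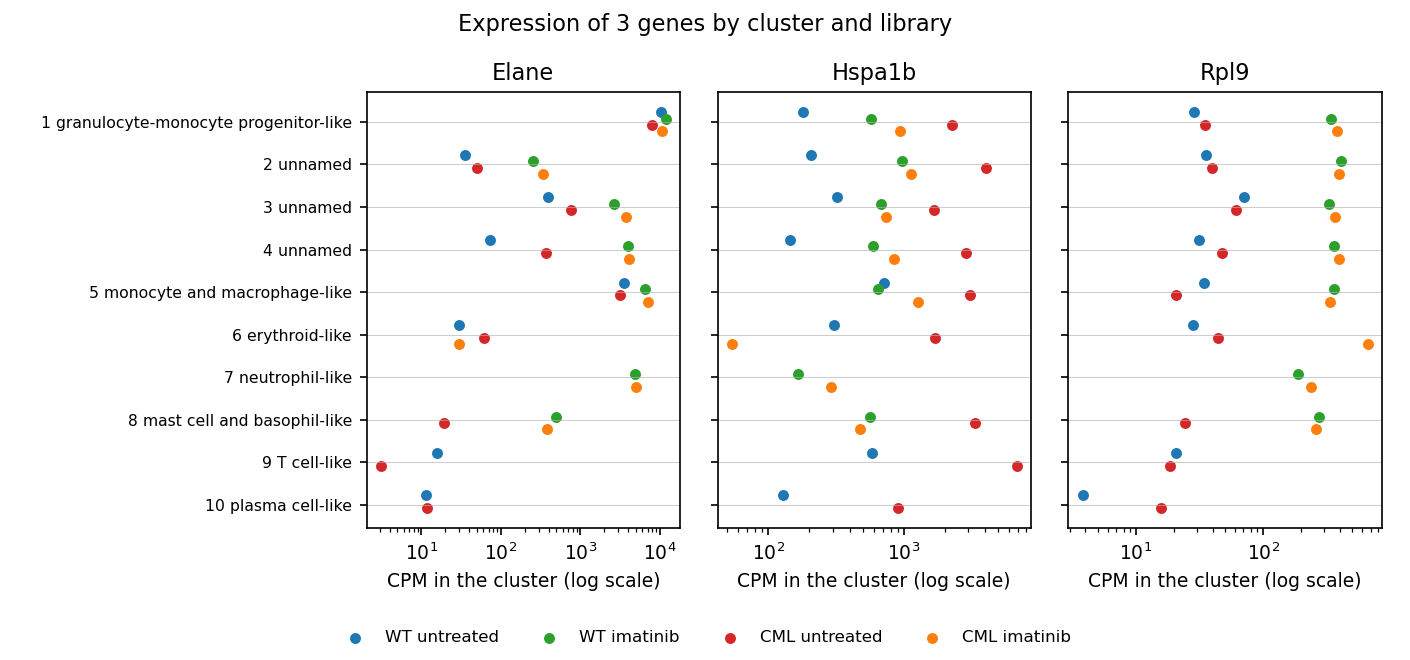
CPM (log scale, horizontal) of Elane, Hspa1b and Rpl9 in each cluster (vertical axis), with 1 point per library; cells of a library in a cluster are summed. Hspa1b is at 6809 CPM in CML untreated against 586.6 CPM in WT untreated T cell-like cells, and Rpl9 at 341.6 and 379.7 CPM in the WT and CML imatinib granulocyte-monocyte progenitor-like cells.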

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

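All tests in this part were chosen after the data had been examined, although thinning all cells to 500 UMIs was set with the design; only for the thinning tests of the granulocytic and heat shock patterns was the prediction written before the value of the test was seen.

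Genes named for the difference of the responses stand out here where imatinib went with at least a 2-fold higher level in one genotype and at least a 2-fold lower level in the other; the difference itself was not tested, since each group has 1 library. Hbb-bs differed by 9.003 (7.498 in CML and -1.505 in WT), Hbb-bt by 8.32 (4.51 and -3.81) and Aqp1 by 5.82 (2.58 and -3.25). Rhd differed by 5.39 (3.05 and -2.34) and Ermap by 4.4 (1.85 and -2.55). Xist differed by -5.70 (-4.64 and 1.05). In WT only Aqp1 reached 50 CPM in either library; Hbb-bs fell from 86 to 19 UMIs there and Xist went from 20 to 26, with an interval of 0.16 to 1.97 on the log2 scale, so these WT values would not pass the size rule.

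Granulocyte-monocyte progenitor genes were higher, and stem and lymphoid progenitor genes lower, in both imatinib libraries. The lower UMI floor of these libraries, and the weight of deep cells in the sums, are argued against as the source. In cells of at least 1000 UMIs thinned to 500, the median of the granulocyte-monocyte progenitor list in WT was 2.38. Thinning keeps the expected share of each gene in a cell, so it cannot test other effects of depth. Free granulocytic RNA in every droplet is argued against as the whole source. Elane was 23.7 times higher in granulocyte-monocyte progenitor-like than in mast cell and basophil-like cells of the WT imatinib library. Elane is also a marker by which the former cluster was named, so this ratio cannot exclude a smaller part of free RNA. A sorted population, preparation or counting that differed between untreated and imatinib libraries stays open: Rpl9 reached a log2 ratio of at least 3.31 in both genotypes, and treatment and preparation cannot be told apart with 1 library each. An effect of the drug on the marrow also stays open, as the design names it and these libraries do not test it.

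Heat shock and immediate early genes were higher in the CML untreated library. Other cell types as the whole source are argued against, since the Hspa1b log2 ratio was 4.27 within the largest untreated cluster alone. A larger weight of deep cells in the sums is argued against by a ratio of 3.75 with cells thinned to 500 UMIs. Other effects of more UMIs per cell cannot be tested by thinning, which keeps each gene's expected share in a cell. Sex of the mice stays open and cannot be told apart from genotype, because only 6 cells of the CML untreated library had a Y-linked UMI and no Xist UMI. Leukaemia itself, cell states finer than that cluster and handling of the sample before capture stay open as well and were not tested.

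Erythroid genes were higher in the CML imatinib library than in the others. Free haemoglobin RNA in every droplet is argued against, since 97.8% of the Hbb-bs UMIs lay in erythroid-like cells. Erythroid cells from other mice than the rest of the library are a candidate explanation: Xist was 45.05 times higher in the erythroid-like than in the granulocyte-monocyte progenitor-like cells, and Y-linked genes were at 0.173 of their level there. The test was chosen after the pattern was seen, so this is a hypothesis. An effect of the drug on leukaemic red cell progenitors was not tested.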

How the results depend on the processing

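The alternatives named below as added were chosen after seeing the data. No paired analysis was possible because each group has 1 library and all carry replicate number 1. Among named genes, 687 of 707 values under the alternatives chosen with the design kept direction and at least a 2-fold size, 14 lost the size and 6 reversed; under added alternatives 385 of 404 kept both, 16 lost the size and 3 reversed. Of list medians, 1444 of 1549 kept their call under the former (46 gained one, 53 lost it and 6 reversed) and 728 of 789 under the latter (35, 21 and 5). Leaving out the cell filter, scaling without ribosomal, mitochondrial and haemoglobin genes, at least 1000 UMIs per cell and leaving out the top 5% of doublet scores (added) kept every count of genes and called lists within 1.5 times; leaving out Scrublet doublets left out 0 cells, tests nothing and is not in these tallies. In what follows counts are genes at least 2-fold higher and lower, in the order CML versus WT untreated (20 and 15), imatinib versus untreated in CML (401 and 339) and in WT (310 and 223), CML versus WT imatinib (91 and 7), and the difference of the responses (97 and 41). Where no reason is given, the cause was not tested. TMM scaling, which takes 1 factor per library, gave 23 lower in the first, 202 higher and 716 lower in the second, 473 lower in WT, and 55 higher and 12 lower for CML versus WT imatinib; the lists called higher in untreated CML were 3 in place of 6. The mean of single-cell CPM gave 36 higher for CML versus WT imatinib and 37 higher for the difference. Thinning to 500 UMIs gave 36 higher and, for the difference, 79 lower, and the plasma cell median of the difference reversed to -0.16. Leaving out mature-cell clusters gave 25 higher and 3 lower for CML versus WT imatinib and 33 and 22 for the difference, with 9 lists called higher in place of 4 and 1 lower in place of 6. It reversed, for CML versus WT untreated, the erythroid list (-0.17), the mast cell list (-0.60), Cpa3 (-0.62) and Ighg2b (1.67), for imatinib in CML the erythroid list (-1.11) and the B cell list (0.56), for CML versus WT imatinib Prss34 (0.36), and for the difference the mast cell list (1.25), Cma1 (1.17), Tpsb2 (2.99) and Jchain (0.76); the cells left out carry these genes. Leaving out plasma cell-like and T cell-like cells (added) gave 9 lower in untreated CML and 4 lower for CML versus WT imatinib, and reversed Ighg2b (1.77) and Jchain in the difference (0.53). Cells of at least 1000 UMIs thinned to 500 (added) gave 360 lower in WT, 37 higher for CML versus WT imatinib and 79 lower for the difference. Lists called higher were 8 in place of 5 in WT and 7 in place of 4 for CML versus WT imatinib, and lists called lower there 3 in place of 6. Reversed were the CML stem cell list for CML versus WT imatinib (0.0903) and, for the difference, the megakaryocyte list (0.0182), the plasma cell list (-0.10) and Tpsb2 (0.36). Leaving out the erythroid-like cluster (added) gave 30 higher for CML versus WT imatinib and 31 for the difference, 10 lists called higher and 1 lower for the former and 11 higher in place of 7 for the latter; the erythroid list reversed for CML versus WT untreated (-0.15) and for imatinib in CML (-1.32). Expression floors change which genes are counted: at 20 CPM and 20 UMIs the counts were 26 lower in untreated CML, 771 and 546, 547 and 407, 199 and 15, and 229 and 78. With no CPM floor and at least 10 UMIs they were 3133 and 218, 4225 and 1985, 2973 and 1584, 2526 and 236, and 1934 and 2036. Lists over genes with at least 50 CPM, which hold fewer genes, were called lower 3 times in place of 7 in untreated CML, 11 in place of 19 for imatinib in CML and 2 in place of 6 for CML versus WT imatinib; a list left with under 3 genes has no median. Leaving out immunoglobulin and sex-linked genes (added) gave 8 lower in untreated CML and 4 lower for CML versus WT imatinib. Within the largest untreated cluster (added) 8 genes were lower in untreated CML, and within the granulocyte-monocyte progenitor-like cluster (added) 19 were higher and 3 lower for CML versus WT imatinib. Genes 2-fold apart in all 16 pairs of file parts (added), each with fewer cells, were 13 and 3, 144 and 141, 188 and 137, and 8 and 4. Leiden resolution 1.0 gave 17 clusters in place of 10. It put 45.2% of CML imatinib, 1.48% of CML untreated, 51.2% of WT imatinib and 2.145% of WT untreated cells in granulocyte-monocyte progenitor-like clusters, 5.05% and 4.26% of CML and WT untreated cells in erythroid-like, 2.88% and 8.335% of CML and WT imatinib cells in monocyte and macrophage-like, and 13.04% and 6.425% in neutrophil-like clusters. At this resolution the untreated libraries differed more in their unnamed clusters: cluster 1 held 46.1% of WT and 16.8% of CML untreated cells, cluster 5 held 2.57% and 34.9%, and a lymphoid-primed progenitor-like cluster 19.9% and 16.4%. Centring within each library gave granulocyte-monocyte progenitor-like shares of 3.03% in CML untreated and 55.1% in WT imatinib, monocyte and macrophage-like shares of 2.16% in CML imatinib, 36.8% in CML untreated, 4.82% in WT imatinib and 37.2% in WT untreated, a mast cell share of 0.066% in WT untreated and 0 T cell-like cells in WT imatinib. The largest untreated cluster was then named megakaryocyte and platelet-like, with 49.9% and 48.1% of WT and CML untreated cells, and erythroid-like cells split into a cluster of 251 CML and 15 WT imatinib cells and another of 114 CML and 65 WT untreated cells. With at least 1000 UMIs per cell, granulocyte-monocyte progenitor-like shares were 68.4% in CML imatinib, 3.40% in CML untreated, 78.3% in WT imatinib and 4.39% in WT untreated, monocyte and macrophage-like shares 2.305%, 21.9%, 5.925% and 16.4% in that order, neutrophil-like shares 14.97% and 5.65% in the CML and WT imatinib libraries, the mast cell share 0.066% in WT untreated and the T cell-like share 0 in WT imatinib. The largest untreated cluster, there again named megakaryocyte and platelet-like, held 70.6% and 64.8% of WT and CML untreated and 6.80% and 5.75% of WT and CML imatinib cells. The G2 and M phase share in the WT untreated, WT imatinib, CML untreated and CML imatinib libraries was 80.4%, 83.5%, 88.5% and 81.2% without thinning, 65.6%, 80.8%, 68.2% and 79.5% with at least 1 UMI, 30.3%, 45.4%, 32.1% and 43.6% with at least 3 UMIs, and 60.1%, 81.2%, 64.5% and 81.5% with thinning to 1000 UMIs, where 1318 WT imatinib and 2059 CML imatinib cells were left out. Depth limits what the imatinib libraries show, with medians of 1486 and 1198 UMIs per cell.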

Other observations

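All comparisons within clusters and the single genes in this part were chosen after the data were seen. Within the largest cluster of the untreated libraries (2070 CML and 2125 WT cells), 15 of 3871 genes were at least 2-fold higher and 8 at least 2-fold lower in CML. At Leiden resolution 1.0 the untreated libraries lay largely in different clusters (cluster 1 with 46.1% of WT and 16.8% of CML cells, cluster 5 with 2.57% and 34.9%), so the cells compared here need not be of the same state. The chaperone gene Hspa1b was at a log2 ratio of 4.27, Hspa1a was 11.7-fold higher, Fosb was 3.78-fold, Klf2 2.93-fold, Dusp1 2.71-fold and Fos, the partner of Jun in AP-1, 2.51-fold higher. The immediate early list had a median of 1.103 and the heat shock list 0.80. Irf8 was 2.58-fold lower, and so was Clec12a, a myeloid lectin gene, by 2.34-fold. Ly6a, lower by 2.01-fold over whole libraries, was at -0.07 within this cluster, Kit at 0.04, Abl1 at 0.21 and Hes1 at -0.99. Hspa1b was at 6809 CPM in CML against 586.6 CPM in WT in T cell-like cells, 914 against 127.5 CPM in plasma cell-like cells, and 2265 against 182 CPM in granulocyte-monocyte progenitor-like cells.

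Within the granulocyte-monocyte progenitor-like cluster of the imatinib libraries (2635 CML and 2444 WT cells), 19 of 3690 genes were at least 2-fold higher and 3 lower in CML. The mast cell gene Cpa3 was 5.50-fold higher, Anxa1, an anti-inflammatory annexin gene, 3.84-fold, Camp 2.41-fold and the metalloprotease gene Adam9 2.26-fold. Ctse, which encodes cathepsin E, was at -4.82. The mast cell list had a median of 1.43, the erythroid list 1.07, the neutrophil list 0.75, the HSC list 0.55 and the granulocyte-monocyte progenitor list -0.06. The mitochondrially encoded list had a median of 0.49 and the immediate early and dissociation list 0.48, both above all random lists, so handling or RNA quality stays open. Free RNA of mast and erythroid cells in these droplets was not tested. Elane was at 10660 CPM in CML and 11800 CPM in WT, and Mpo differed by 0.02 on the log2 scale.

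Many genes differed between untreated and imatinib libraries inside clusters as well. For imatinib versus untreated, 324 of 2820 genes were at least 2-fold higher and 101 lower in the granulocyte-monocyte progenitor-like cells of CML, and 148 and 46 of 2990 in those of WT, against 73 and 99 untreated cells. In the largest untreated cluster 12 were higher and 794 lower of 2335 in CML and 14 and 583 of 2240 in WT. The imatinib side had only 41 CML and 67 WT cells with 58328 and 83716 UMIs, against 13244762 and 8323890 untreated UMIs. There few genes could reach 50 UMIs, and a gene near 50 CPM has few UMIs. Counting error can therefore make lower calls in this cluster, and their number was not estimated. Rpl9 was at 28.7 and 35.2 CPM in the granulocyte-monocyte progenitor-like cells of the WT and CML untreated libraries and at 341.6 and 379.7 CPM in those of the WT and CML imatinib libraries. In the largest untreated cluster it was at 35.8 and 39.9 CPM in the untreated against 406.1 and 394.3 CPM in the imatinib libraries. Gm42418, a transcript that overlaps ribosomal RNA, was at 1133, 4369, 2476 and 9129 CPM in the WT untreated, WT imatinib, CML untreated and CML imatinib libraries. Immunoglobulin genes took 2.42%, 0.102%, 0.692% and 0.00799% of the UMIs in that order.

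Values also differed along the columns of some files, split here into 4 parts in column order. In the CML imatinib library Xist was at 2.92, 97.7, 181.5 and 59.1 CPM, Hbb-bs at 16.6, 361, 1943 and 545 CPM, and erythroid-like cells numbered 3, 29, 143 and 82. In the CML untreated library the median UMI count per cell was 7988, 7738, 4086 and 3718. In the WT untreated library it was 3918, 3753, 3543 and 3483. Xist in the CML imatinib library was at 427 CPM in erythroid-like, 80.9 CPM in cluster 4 and 9.49 CPM in granulocyte-monocyte progenitor-like cells. Of the 2339 Cxcl12 UMIs of that library, 2224 lay in the 868 cells of cluster 4. In the whole library 74 of 5139 cells had at least 1 Cxcl12 UMI. In cluster 4, 25 cells had at least 3 UMIs from the stromal list, so the stromal genes rest on few cells.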
